A study of Lathyrus oleraceus subsp. biflorus and Lathyrus oleraceus and [Pisum sativum] subsp. abyssinicum with 117 samples.

How the data were processed

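Gene expression was measured by RNA sequencing in 117 libraries of pea seed tissue, 67 of seed coat and 50 of embryo, at 5 developmental stages labelled D1 to D5. The plants belonged to 6 accessions. JI64, JI261 and JI1794 were wild peas (Pisum elatius), Cameor (a cultivar) and JI92 (a landrace) were domesticated peas (P. sativum), and PI358617 was an Ethiopian pea (P. abyssinicum). A main set of 106 libraries covered all 6 accessions, and 11 further seed coat libraries of JI64 and JI92 at D1, D2 and D4 carried the year 2017 in their labels. Tissue, accession, stage and set defined 60 groups, of which 57 held 2 libraries and 3 held 1 library. The labels do not say whether the 2 libraries of a group came from separate plants, so p-values from single libraries measure the spread between these samples, which may be technical.

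Per the labels' protocols, plants grew in a glasshouse without treatment, total RNA was enriched for messenger RNA with oligo(dT) beads, and complementary DNA was primed with random hexamers. Whether the libraries kept the strand of the transcript is not given in the sources used here. The series' design text states that reads were mapped to the reference genome of the cultivar Cameor, and the submitters' processing notes name HISAT2 2.1.0 and StringTie 2.1.0 without the role of each. The rule by which reads were counted, the handling of reads that match several genes and the way loci outside the annotation were defined are not given in the sources used here. The authors deposited a table of read counts per gene, which are whole numbers that were not normalized. They also deposited a table of FPKM values, fragments scaled by gene length and by the mapped total, for the same genes and libraries.

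Both tables listed 59594 features. Of these, 27650 carried identifiers of the series Psat1g to Psat7g, 4207 of the series Psat0s, and 27737 began with Ps_DOR2genes. The last kind is called loci outside the annotation below. Of all rows, 10 repeated an identifier of another row, were kept as separate features and were left out of the lists. The files do not pair identifiers with gene names. None of the identifiers (0) matched the supplied table of 65673 RefSeq genes, which belongs to another pea assembly (ZW6), so keyword lists of gene families prepared for this tissue could not be applied and no gene is named by function. Near-identical gene copies could not be marked, because no sequence of the build was used here, and counts of such copies may be split between them.

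Library totals ran from 56.97 M counts upward, with a median of 66.1 M (M, mega). Intervals of shares are exact 95% binomial intervals (Clopper-Pearson), and a count of 0 was read as allowing up to 3 counts over the libraries of the group. Such intervals and limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Replicates were compared by Spearman's rank correlation of log2 CPM (counts scaled by the library total) and by their counts over genes with at least 100 counts in the pair. For the latter, the median squared deviation from an equal split of each gene's counts, after scaling by the median ratio, was divided by the median of a chi-square distribution, so that sampling noise alone gives a ratio near 1. The lowest ratio among the 57 pairs was 5.42, and every library was kept as a sample of its own.

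The main tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with trended dispersions and robust fitting, TMM normalization, the default filter on low counts, Benjamini-Hochberg adjustment, threshold 0.05). Because the question concerned accessions, counts were summed per accession, or per accession and stage or tissue, and the sums were the replicates. The comparison of wild with domesticated seed coats used D1, D3, D4 and D5, the stages at which all 5 accessions were sampled, and each stage was also tested alone. At D5 Cameor and JI92 had 1 library each and the wild accessions 2 each. D5 therefore weighed more in the wild sums, so stage weight and class were not fully separate over all stages. The embryo comparison and the interaction of tissue and class used D3 and D4. PI358617 took no part in these comparisons. Seed coat against embryo used all 6 accessions at D3 and D4 with accession as a term. Stages were compared with accession and stage as terms. JI64 against JI92 in both sets, and all pairs of accessions, used single libraries as replicates.

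The design, its alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Alternatives replaced TMM by RLE, removed the low-count filter, used DESeq2 1.42.0, used limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), took single libraries as replicates, left out each accession and each replicate number in turn, added the 2017 libraries, counted PI358617 with the domesticated accessions, or required a log2 fold change of at least 1. A limma-voom fit on accession-by-stage sums took accession as a random block. After the data had been seen, fits without 3 JI64 libraries that stood apart, stage steps with their alternatives, list tests without the JI92 embryos at D3 and at D4 alone, the list of loci outside the annotation and the search for separating genes were added.

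Each of the 5 main comparisons was tested on simulated counts, drawn from negative binomial distributions with the means, library sizes and trended dispersions of the real sums, with 200 genes changed. The changed genes were drawn from the more abundant genes only, so recovery at low levels was not measured. For the comparison of wild with domesticated seed coats the test recovered 7% of 4-fold and 65% of 16-fold changes, with 3 false calls. The embryo comparison recovered 0% and 29%, and the interaction 0% and 26%. Seed coat against embryo recovered 57% and 99%, and D5 against D1 in the seed coat 67% and 99%. DESeq2, run on the simulated counts of the first comparison, made 805 false calls.

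Gene lists were defined in the PI358617 libraries alone, which were then left out of every test of a list. The seed-coat-enriched and embryo-enriched lists held the 300 genes with the largest change between the tissues over the 5 stages (adjusted p under 0.01), and the early and late seed coat lists the 300 genes that fell or rose most from D1 to D5. Lists were tested with camera at the preset correlation of 0.01, camera with an estimated correlation, and fry, each 2-sided and adjusted over the 5 lists. The share of counts taken by the 50 most abundant embryo genes of PI358617 that differed at least 32-fold between its tissues served as a measure of embryo material. To see how far embryo material moved late genes and the stage score, mean CPM profiles of a seed coat and of an embryo were mixed, a computation added after the data were seen. The share of embryo was the share of counts in the abundant embryo genes of the target seed coat over that of its embryo. The stage score of a library was the mean log2(CPM + 1) of late genes minus that of early genes.

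Named genes were, per comparison, the 2 with the largest log2 fold change in each direction among those past the threshold that moved the same way in every accession and had a mean of at least 2 CPM. Where no gene passed the threshold, genes at least 4-fold apart between every accession of one class and every accession of the other, with a mean of at least 2 CPM, were counted, and the same count was made for every other split of the 5 accessions into 3 and 2. The position of PI358617 was therefore taken over these separating genes, not over called genes. Folds against a group without any count are lower bounds against the limit of 3 counts over the group. The fitted log2 fold changes of such genes depend on the tool and are not estimates of the fold.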

Results

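Messenger RNA was measured in seed coats and embryos of 6 pea accessions over 5 developmental stages, to ask how gene expression in the seed coat differs between wild and domesticated peas. The seed coat is the maternal tissue that encloses the embryo. The main set held 106 libraries, 56 of seed coat and 50 of embryo, and 11 further seed coat libraries of JI64 and JI92 were labelled 2017. Seed coats of JI261 had no library at D2 in the set analysed here, and embryos at D1 came from 3 accessions only. Library totals had a median of 67.4 M counts (M, mega) in the seed coat and of 65.2 M in the embryo. They ran from 57.2 M in the seed coat and 56.97 M in the embryo to 96.4 M, apart from the largest library, replicate 1 of the JI64 seed coat at D5. The 2 replicates of a group had a median Spearman correlation of 0.961 over 57 groups.

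Genes enriched in the PI358617 seed coat marked the tissue of nearly all libraries. In the 5 accessions that did not define the list, the 300 seed-coat-enriched genes took 1.70% to 15.5% of the counts in all but 3 seed coat libraries, and at most 0.0478% in any embryo library. Of these 3 seed coat libraries, all of JI64, replicate 2 at D1 held 0.0350% of its counts in these genes (95% exact interval 0.0346 to 0.0355), against 10.9% (10.85 to 10.86) in replicate 1. The 50 abundant embryo genes took 12.6% (12.61 to 12.63) of its counts, against 0.516% (0.514 to 0.518) in replicate 1. Its rank correlation with replicate 1 was 0.865, and with replicate 1 of the JI64 embryo at D1 it was 0.958. At D5 the seed-coat-enriched genes took 0.157% (0.156 to 0.158) of the counts of JI64 replicate 1 and 1.59% (1.588 to 1.595) of those of replicate 2. Abundant embryo genes took 4.12% (4.109 to 4.12) of the counts of replicate 2, the highest share among the D5 seed coats. The 2 replicates were closer to each other (0.915) than to any other library. The planned comparisons kept these 3 libraries.

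**Figure D1:**
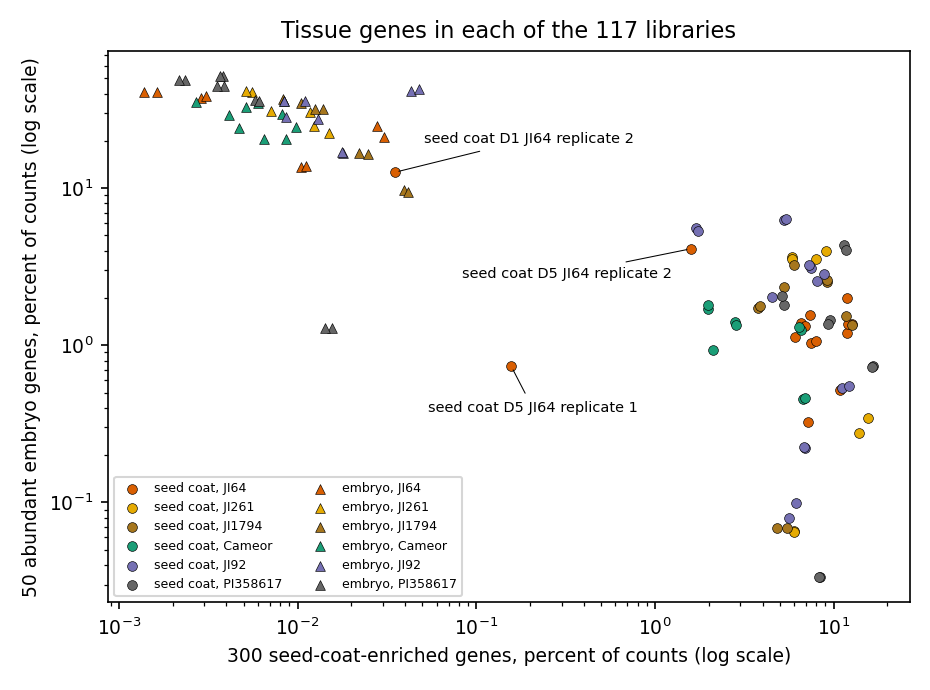
Each point is a library, 67 of seed coat and 50 of embryo, with the share of counts in 300 seed-coat-enriched genes on the horizontal axis and in 50 abundant embryo genes on the vertical axis (percent, log scales), circles for seed coat and triangles for embryo. Replicate 2 of the JI64 seed coat at D1, with 0.0350% and 12.6%, lies among the embryo libraries, replicate 1 of the JI64 seed coat at D5, with 0.157%, lies between the tissues, and replicate 2, with 1.59%, lies at the edge of the seed coats.

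Seed coat and embryo were compared at D3 and D4 over 6 accessions. In all 8947 of 39515 genes differed, 5096 higher in the seed coat and 3851 higher in the embryo (edgeR, adjusted p under 0.05). The locus Ps_DOR2genes.26312 had 2 to 414 CPM in the seed coats (SD 165 CPM, n = 6 accessions) and not 1 count in 24 embryo libraries, and was at least 40450-fold higher in the seed coat (log2 fold change 17.83, SE 0.69, edgeR adjusted p = 0.000428). Psat5g049080 had 11.2 ± 6.27 CPM in the seed coat and no count in the embryo, a level at least 4352-fold higher (edgeR adjusted p = 0.00104). The locus Ps_DOR2genes.8646 was higher in the embryo, with 1625 ± 3244 CPM against 5.37 ± 10.6 CPM (log2 fold change -7.94, SE 0.94, edgeR adjusted p = 0.000528), and ranged from 13.5 to 8224 CPM among the embryos. Ps_DOR2genes.57123 had 4.03 ± 5.12 CPM in the embryo and 0.197 ± 0.447 CPM in the seed coat (log2 fold change -7.16, SE 1.35, edgeR adjusted p = 0.00532). Each of these 4 features moved the same way in every accession, as did 6126 of the genes past the threshold with a mean of at least 2 CPM. With single libraries as replicates Ps_DOR2genes.8646 had adjusted p = 0.0702 (edgeR), and with limma on log2(FPKM + 1) Ps_DOR2genes.57123 had a log2 difference of -0.49 and adjusted p = 0.108. DESeq2 called 13861 genes between the tissues and edgeR on single libraries 16507. With limma on log2(FPKM + 1) the split was 5807 higher and 721 lower in the seed coat, and with a pseudocount of 0.1 it was 7619 and 1201.

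The lists defined in PI358617 were tested in the other 5 accessions. Of 296 seed-coat-enriched genes, 264 were higher in the seed coat (282 adjusted over the list alone), with a median log2 fold change of 9.53, or 9.44 with genes at 0 in one tissue set at their bound. The list passed camera with an estimated correlation (adjusted p = 0.0433). Of 188 embryo-enriched genes, 41 were higher in the embryo (43 adjusted over the list alone) and the median was -2.78. This list passed camera at the preset correlation, with adjusted p = 0.0953 with an estimated correlation. Late seed coat genes split, with 56 of 270 higher in the seed coat and 107 higher in the embryo (198 adjusted over the list alone). Their median was -2.16 and their mean 0.31, camera gave the direction of the median, and the call was lost with an estimated correlation (adjusted p = 0.292). Of 207 early seed coat genes, 22 were higher and 6 lower in the seed coat (23 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). Among 12306 loci outside the annotation, 362 were higher in the seed coat and 404 in the embryo (adjusted p = 0.292 with an estimated correlation).

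Development of the seed coat gave the largest number of differing genes among the 5 main comparisons, whose replicates were sums per accession. The fits differed in their number of sums. With single libraries as replicates the order turned, with 15581 genes between D1 and D5 against 16507 between the tissues. Between D1 and D5, 12726 of 40094 genes differed over the 6 accessions, with 5119 higher and 7607 lower at D5 (edgeR, adjusted p under 0.05). Psat6g160400 rose from no count in 12 libraries at D1 to 111 ± 194 CPM at D5 (SD, n = 6), at least 35680-fold higher (log2 fold change 20.42, SE 2.81, edgeR adjusted p = 2.43e-05). This mean rested largely on JI1794, with 501 CPM against 0.600 to 90.9 CPM in the other 5 accessions. As D1 had no count, the fitted log2 fold change of this gene depends on the tool, and DESeq2 gave 13.86. Psat7g264320 rose from no count to 187 ± 268 CPM, at least 59740-fold higher (edgeR adjusted p = 0.000366). Here JI64 weighed most, with 699 CPM in its 2 libraries with few seed coat transcripts, against 0.622 to 212 CPM in the other 5 accessions (adjusted p = 0.000581 without these libraries). Psat0s4925g0080 fell from 123 ± 121 CPM to no count in 10 libraries at D5, at least 24500-fold lower (log2 fold change -17.37, SE 2.60, edgeR adjusted p = 5.38e-05), and Psat0s2917g0120 fell from 40.4 ± 32.9 CPM to no count, at least 8070-fold lower. Leaving out the 3 JI64 libraries gave 13135 genes. With limma on log2(FPKM + 1) the split was 3097 higher and 8877 lower, and with a pseudocount of 0.1 it was 3320 and 9670.

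The early and late lists of PI358617 moved as in that accession when tested in the other 5. Of 293 early seed coat genes, 264 fell and 1 rose from D1 to D5 (281 adjusted over the list alone), with a median log2 fold change of -9.08, or -8.20 with genes at 0 on one side set at their bound (camera, adjusted p = 0.0105 with an estimated correlation). Of 273 late genes, 172 rose (187 adjusted over the list alone), with a median of 5.51, or 5.37 with bounds (adjusted p = 0.0152 with an estimated correlation). Without JI64 the adjusted p of the late list with an estimated correlation was 0.0526. In the seed coats of Cameor, JI92, JI1794 and JI261 the abundant embryo genes took 0.0645% to 0.461% of the counts at D1 and 0.938% to 3.64% at D5. The late list took 26.1% to 61.7% of the counts in the D5 embryos of these accessions and 3.17% to 10.7% in their D5 seed coats. How far embryo material could move late genes was computed by mixing the D1 seed coat of each of these 4 accessions with its D5 embryo. The share of embryo was the 3.84% to 18.1% that the abundant embryo genes gave. The mean level of late genes on the log2(CPM + 1) scale was 0.33 to 1.37 in the D1 seed coats, 2.66 to 2.96 in the mixtures and 3.28 to 4.15 in the D5 seed coats. In the D5 seed coats 192 of the 300 late genes lay above the mixture in JI92, 184 in JI1794, 164 in Cameor and 147 in JI261. Noise alone would place genes evenly on both sides of the mixture, and the lower of these counts were near such an even split. Of 56 late genes higher in the seed coat than in the embryo, 41 rose from D1 to D5 with a median of 6.32, as did 76 of 107 higher in the embryo (6.58) and 54 of 106 others (3.73), and none (0) fell. Of 298 seed-coat-enriched genes, 63 rose and 98 fell, and of 180 embryo-enriched genes 6 rose and 25 fell, and neither list passed camera. The embryo-enriched median moved from -0.78 to -1.19 without the 3 JI64 libraries, and the median of loci outside the annotation to -0.39 with a mean of -0.59. Of 12696 loci outside the annotation, 498 rose and 715 fell. With all libraries their median was -0.14 and their mean -0.35, while camera ranked them upward without passing (adjusted p = 0.407).

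The stage score, the mean level of late minus early genes, differed between accessions under the same stage label. At D1 the seed coat score was 0.018 ± 0.0018 in Cameor (SD, n = 2 libraries) and -2.86 ± 0.11 in JI92. At D3 it was -0.20 ± 0.0011 in JI261 and 3.00 ± 0.11 in JI64. The abundant embryo genes differed in these pairs too. At D1 they took 0.455% and 0.461% of the counts in the 2 Cameor libraries (95% exact intervals 0.453 to 0.456 and 0.459 to 0.462) and 0.0797% and 0.0996% in those of JI92 (0.0791 to 0.0804 and 0.0988 to 0.1004). At D3 they took 0.344% and 0.276% in JI261 (0.343 to 0.346 and 0.275 to 0.278) and 1.33% and 1.57% in JI64 (1.331 to 1.337 and 1.562 to 1.568). They did not follow the score throughout, since at D3 JI92 had a score of 2.11 ± 0.0042 and 2.55% and 2.83% (2.544 to 2.551 and 2.824 to 2.832). JI92 at D1 mixed with 2.22% of the Cameor embryo scored -2.37, and JI261 at D3 mixed with 3.54% of the JI64 embryo scored 0.98, both below the scores of Cameor and JI64. The score of embryo genes at D3 was 0.96 ± 0.029 in JI261, 4.07 ± 0.0038 in Cameor and 5.72 ± 0.0077 in JI1794. In JI1794 the embryo score did not rise further, with 5.33 ± 0.023 at D4 and 5.26 ± 0.016 at D5.

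**Figure D2:**
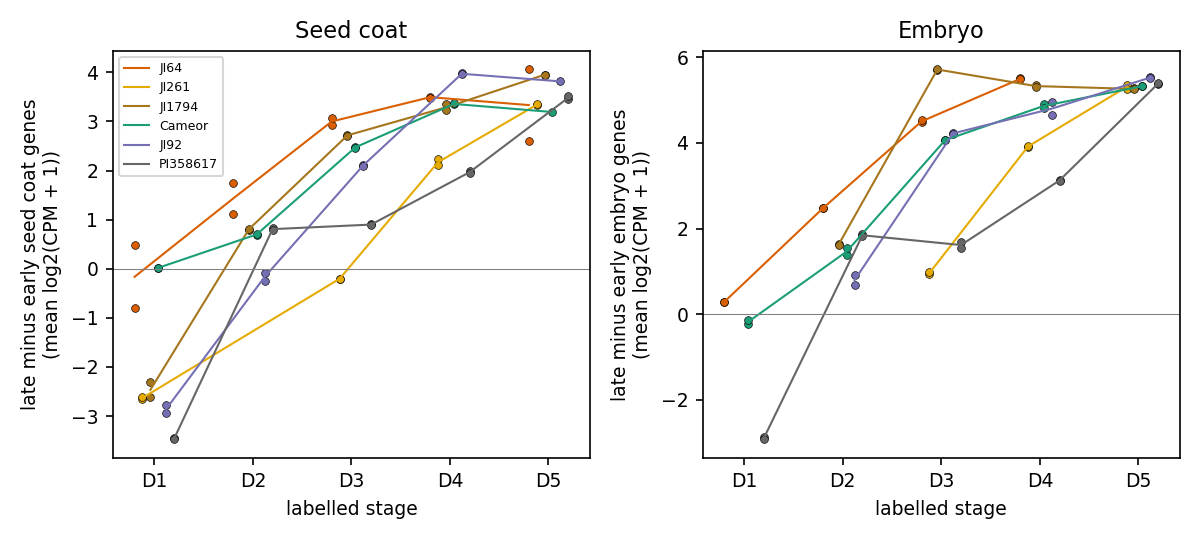
Mean log2(CPM + 1) of 300 late minus 300 early genes of PI358617 against the labelled stage, in the seed coat (left) and with embryo lists in the embryo (right), each point a library of the main set and each line the mean of an accession, PI358617 included although it defined the lists. At D3 the embryo scores run from 0.96 in JI261 to 5.72 in JI1794.

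Single steps between stages changed fewer genes than the whole course. In the seed coat 514 genes differed from D1 to D2 (157 rose, 357 fell), 1033 from D2 to D3 (326 rose, 707 fell), 252 from D3 to D4 (207 rose, 45 fell) and 221 from D4 to D5 (12 rose, 209 fell). In the embryo 1122 genes differed from D2 to D3 (653 rose, 469 fell), 11 rose from D3 to D4, and none (0) passed from D4 to D5 in edgeR, where 4746 genes had an unadjusted p under 0.05 and no other tool was run. From D2 to D5, 12392 of 35373 embryo genes differed, 5917 rising and 6475 falling. The 2 tissues shared 1862 genes that rose and 2478 that fell from D2 to D5 among the 31750 genes tested in both, and 140 and 191 genes moved in opposite directions. Both tissues came from the same accessions under the same stage labels, and the share of abundant embryo genes in the seed coats changed as well. Abundant embryo genes took 0.535% and 0.550% of the counts in JI92 at D2 (95% exact intervals 0.534 to 0.537 and 0.549 to 0.552) and 2.04% at D5 (2.036 to 2.043). In Cameor they took 1.25% and 1.30% at D2 (1.248 to 1.253 and 1.299 to 1.303) and 0.938% at D5 (0.936 to 0.940). These genes fell within the embryos too, so their share in a seed coat does not measure embryo content alone. In the JI92 embryos they took 27.6% and 28.4% at D2 and 16.8% and 16.95% at D5. In the Cameor embryos they took 32.8% and 35.9% at D2 and 24.7% and 24.2% at D5. The counts of single steps depended on the accessions used: leaving out 1 accession gave 0 to 1173 genes from D1 to D2 in the seed coat, 0 to 1865 from D2 to D3, 0 to 228 from D3 to D4 and 0 to 624 from D4 to D5. Without the 3 JI64 libraries the counts were 746, 2685, 1088 and 229, and leaving out 1 accession gave 0 to 3060 genes in the embryo from D2 to D3 and 0 to 10 from D3 to D4. Without the low-count filter the seed coat steps gave 259 genes from D1 to D2, 615 from D2 to D3 and 112 from D4 to D5, and the embryo steps 0 from D2 to D3 and 5 from D3 to D4. With RLE the seed coat step D4 to D5 gave 123 genes and the embryo step D3 to D4 gave 5.

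Wild and domesticated seed coats were compared with the accession as the unit, 3 wild against 2 domesticated, over D1, D3, D4 and D5. These were 24 wild and 14 domesticated libraries. Cameor and JI92 had 1 library each at D5, so D5 weighed less in their sums than in the wild ones. No gene (0 of 35034) passed the threshold in edgeR, where 1437 genes had an unadjusted p under 0.05 (4.10%). Limma on FPKM called 0 genes with either pseudocount, a limma-voom fit with accession as a random effect called 661 (95 higher and 566 lower in wild), edgeR without the low-count filter called 2, and DESeq2 called 2776 (1502 higher and 1274 lower), where the other splits of the 5 accessions gave 2004 to 3164. Without the 3 JI64 libraries edgeR on the sums also called 0 genes (of 34681, 1396 at an unadjusted p under 0.05). These include all JI64 libraries at D5, so the JI64 sum then lacked a stage that the other sums held. A further fit, chosen after the data were seen, left out D5 of every accession and replicate 2 of JI64 at D1. It called 0 of 33720 genes (1240 at an unadjusted p under 0.05). With single libraries as replicates, a test of these 5 accessions and not of the classes, 12297 genes differed, 4323 higher and 7974 lower in wild, and with single libraries but without the 3 of JI64 14831 did. At single stages edgeR called 0 genes at each of D1 to D5, with 1303, 2224, 1358, 1040 and 922 genes at an unadjusted p under 0.05. Without the low-count filter it called 18 genes at D3, 11 at D4 and 60 at D5. In simulated data of this design 65% of 16-fold but 7% of 4-fold changes were recovered, among the more abundant genes alone.

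Seed-coat-enriched genes tended upward in the wild seed coats, with 183 of 298 positive and a median log2 difference of 0.38, but none passed over all genes and 1 when adjusted over the list alone. The list passed camera at the preset correlation (adjusted p = 0.0208) and had adjusted p = 0.970 with an estimated correlation. Single stages differed, with medians of -0.22 at D1, 0.14 at D2, 1.03 at D3, 0.57 at D4 and 0.42 at D5 (ranked downward by camera), and of 0.18 at D1 without JI64 replicate 2. At D5 both JI64 libraries hold few seed coat transcripts, and without them the median was 0.71 and camera passed the list upward (184 of 280, adjusted p = 0.000849, and 0.697 with an estimated correlation). Camera passed the list at D3 (220 of 296 positive, adjusted p = 1.53e-06, and 0.416 with an estimated correlation) and at D4 (197 of 295, adjusted p = 2.65e-06, and 0.672 with an estimated correlation). Early genes were divided between the directions, with 150 of 296 positive, a median of 0.05 and 0 genes adjusted over the list alone, although camera ranked them upward (adjusted p = 0.0354 at the preset and 0.970 with an estimated correlation). With JI64 left out 171 of 296 were positive, with a median of 0.32 (adjusted p = 8.00e-06, and 0.722 with an estimated correlation). At D2 they were ranked downward, with 86 of 253 positive and a median of -0.90 (adjusted p = 0.000875, and 0.795 with an estimated correlation), and at D3 upward, with 128 of 186 positive and a median of 1.17 (adjusted p = 0.0109, and 0.819). At D1 they were ranked upward with a median of 0.12 (adjusted p = 0.0112, and 0.879 with an estimated correlation), which was 0.25 without JI64 replicate 2 (adjusted p = 0.00215, and 0.624). The 3 JI64 libraries with few seed coat transcripts belonged to the wild class. Without them, and so without any JI64 library at D5, the median of the seed-coat-enriched list was 0.57. Late genes had a median of -0.19 and a mean of -0.04 while camera ranked them upward. Embryo-enriched genes (median 0.16) and loci outside the annotation (median 0.16) were ranked downward. None of these 3 lists passed over all stages (adjusted p = 0.901 each). At single stages late genes passed at the preset correlation in opposite directions, upward at D2 (182 of 224 positive, median 1.35, adjusted p = 6.27e-10) and D5 (172 of 253, 0.97, adjusted p = 0.00139). They were ranked downward at D4 (82 of 253, -0.73, adjusted p = 0.000275). With an estimated correlation these adjusted p were 0.478, 0.998 and 0.672. The stage scores of single accessions also differed at these stages. At D2 they were 1.43 in JI64 and 0.80 in JI1794 against 0.70 in Cameor and -0.17 in JI92. At D4 they were 2.17 to 3.49 in the wild accessions against 3.36 in Cameor and 3.97 in JI92, and at D5 3.33 to 3.95 against 3.19 and 3.82. The share of counts in abundant embryo genes differed too. At D4 it was 6.30% and 6.34% in JI92 and 1.71% and 1.80% in Cameor, against 1.13% to 3.98% in the wild libraries. At D2 it was 0.535% and 0.550% in JI92 and 1.25% and 1.30% in Cameor, against 1.20% to 1.99%. The part of these shares in the calls of late genes was not tested. At D5 without JI64 the late median was 0.39 (156 of 244, adjusted p = 0.0359, and 0.697 with an estimated correlation), and loci outside the annotation passed downward (1739 of 3808, median -0.19, adjusted p = 0.0359, and 0.697). Embryo-enriched genes were ranked upward at D2 (median 0.55, adjusted p = 0.0132, and 0.287 with an estimated correlation). At D3 they were ranked downward (median -0.88, adjusted p = 0.0180, and 0.654 with an estimated correlation). Without the 3 JI64 libraries the late list had a median of -0.42 and camera turned downward (adjusted p = 0.381), and loci outside the annotation had a median of 0.06. The JI64 sum then lacked D5 while the other sums kept it, and late genes were chosen as higher at D5 than at D1. The turn of the late list therefore cannot be told apart from the loss of this stage. The embryo-enriched list had a median of -0.32 without the 3 JI64 libraries (camera adjusted p = 0.0232, and 0.770 with an estimated correlation). With all JI64 libraries left out it was -0.29 and the list did not pass (adjusted p = 0.0919). The median of loci outside the annotation then turned to -0.29, with 3472 of 7796 positive (adjusted p = 0.0644).

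Some genes separated the classes widely. Of 17583 genes with a mean of at least 2 CPM, 58 were at least 4-fold higher and 122 at least 4-fold lower in every wild accession than in every domesticated one. With 3 accessions against 2, chance sets 20% of genes wholly apart when no gap is asked for. Other splits of the same accessions gave 82 to 274 such genes, the highest with JI1794, JI261 and JI92 against JI64 and Cameor, whose D1 stage scores were -2.86 to -2.47 against 0.02 in Cameor and -0.16 in JI64 (-0.80 without replicate 2, and -2.31 in the JI64 library of 2017). The counts were 67 and 127 without the 3 JI64 libraries, where the JI64 sum lacked D5. Psat5g116080 and Psat6g092880, chosen after their values were seen, had no count in 24 wild seed coat libraries and counts in each of 14 domesticated ones, with 12 ± 6.65 and 7.54 ± 1.89 CPM (SD, n = 2 accessions). Psat7g239960 had 13.7 ± 5.25 CPM in the wild accessions (n = 3) and 0.185 ± 0.261 CPM in the domesticated ones, and Psat6g185280 had 3.48 ± 2.16 and 0.0517 ± 0.0731 CPM. Both were also chosen after their values were seen, and none of these 4 genes passed the test over all genes (edgeR adjusted p = 0.9995). Loci outside the annotation made up 25 of the higher and 58 of the lower genes, 6.23% of the 1332 expressed loci of this kind, against 0.561% of the Psat1g to Psat7g series and 0.921% of the Psat0s series. The Psat1g to Psat7g series made up 82 of the 180 genes here. It made up 184 of 274 in the split with the most genes and 28 of 82 in that with the fewest. A large part of other features was thus not particular to the classes.

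**Figure D3:**
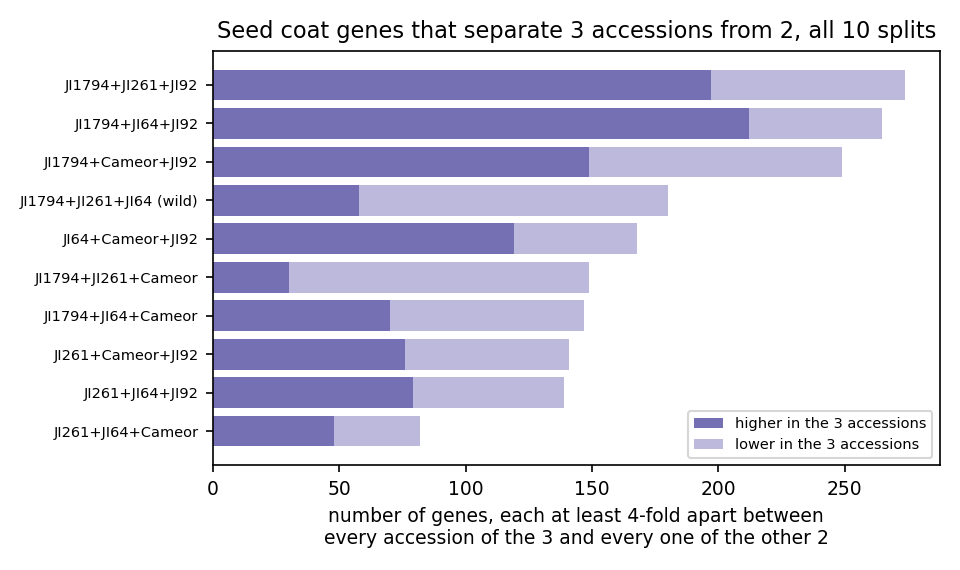
Number of seed coat genes at least 4-fold apart between every accession of a group of 3 and every accession of the other 2, for each of the 10 splits of the 5 accessions, with genes higher and lower in the 3 accessions in dark and light. The wild against domesticated split gives 58 and 122 genes, and the splits range from 82 to 274 in all.

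The Ethiopian pea PI358617 was placed on these genes without having entered their choice. It was nearer the domesticated mean at 27 of the 58 genes higher in wild (46.6%, 95% exact interval 33.3 to 60.1) and at 41 of the 122 genes lower in wild (33.6%, 25.3 to 42.7). Over all 17583 expressed genes the share was 44.3%. Of the lower genes with at least 10 CPM the share was 20% (2 of 10 genes, interval 2.52 to 55.6). At Psat5g116080 PI358617 had 7.74 CPM, as the domesticated accessions, and at Psat6g092880 0.00646 CPM. One accession does not test the species.

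Wild and domesticated embryos, compared at D3 and D4, showed the same kind of picture. EdgeR called 0 of 28091 genes, with 1274 at an unadjusted p under 0.05, limma called 0 with either pseudocount, and DESeq2 called 2625 (1724 higher and 901 lower in wild). With single libraries as replicates 13328 genes differed. Seed-coat-enriched genes had a median log2 difference of -1.10 in the embryo, with 51 of 179 positive and 0 adjusted over the list alone (camera adjusted p = 0.00317, and 0.798 with an estimated correlation). This rested on the 2 JI92 embryos at D3, which held 0.0433% and 0.0478% of their counts in these genes (95% exact intervals 0.0428 to 0.0438 and 0.0472 to 0.0483), the highest shares of all embryos. Without them 88 of 127 genes were positive, the median turned to 1.05 and the list did not pass (adjusted p = 0.147), and at D4 alone the median was 0.63 (adjusted p = 0.129). The other 4 lists did not pass. Embryo-enriched, early and late genes had medians of 0.36, 0.15 and 0.36 and were ranked downward by camera, and loci outside the annotation had a median of 0.37. Genes at least 4-fold apart between the classes numbered 118, with 48 higher and 70 lower in wild. Of genes expressed in both tissues at D3 and D4, 45 were lower in wild by this measure in the seed coat and 51 in the embryo, and 36 were shared. For higher genes the numbers were 10 and 22 with 5 shared. The tissues came from the same accessions, so other splits shared genes as well, 11 to 66 in both directions together against 41 for the classes (2 of 10 splits had at least as many, the real one included).

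The class difference was also compared between the tissues directly. The interaction of tissue and class called 0 of 37310 genes in edgeR, with 1455 at an unadjusted p under 0.05, while limma called 0 with either pseudocount and DESeq2 called 97. Without the low-count filter edgeR called 2 genes, and with single libraries as replicates 10271. The difference between wild and domesticated was more positive in the seed coat than in the embryo for 223 of 296 seed-coat-enriched genes, with a median of 2.21 on the log2 scale and 0 genes adjusted over the list alone. This list passed camera at the preset correlation (adjusted p = 3.04e-11), with adjusted p = 0.425 with an estimated correlation. Without the 2 JI92 embryos at D3 the call ended, with 140 of 296 positive, a median of -0.21, a mean of -0.41 and an upward rank by camera (adjusted p = 0.161). At D4 alone the median was -0.05 (adjusted p = 0.255). For early genes 124 of 207 were positive, with a median of 0.86 (adjusted p = 0.00854, and 0.610 with an estimated correlation). It was 0.50 without the JI92 embryos at D3 (adjusted p = 0.0141, and 0.711 with an estimated correlation) and 1.70 at D4 alone (1.19e-06, and 0.126). Embryo-enriched and late genes and loci outside the annotation had medians of -1.13, -0.58 and -0.77 and did not pass. At D4 alone these medians were -0.54, -1.09 and -0.65, and late genes passed camera downward (adjusted p = 0.0271, and 0.547 with an estimated correlation).

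The wild JI64 and the landrace JI92 were sampled in 2 sets, of which the labels give only the year 2017 for one, and the recurrence of their difference was measured. In the main set 14767 of 39851 genes differed between them over D1, D2 and D4 (7993 higher and 6774 lower in JI64, edgeR on single libraries), and in the 2017 set 14336 did (8232 and 6104). Both sets called 5429 genes higher and 3947 lower in JI64, against 1651 and 1038 for independent lists, and 402 genes in opposite directions. Of the genes called in the main set, 89.0% had the same sign in the 2017 set. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.859. The difference itself differed between the sets for 1902 genes. Between 2017 and the main set 397 genes differed within JI64 and 5076 within JI92. At D4 the seed-coat-enriched genes took 1.70% and 1.74% of the counts of the 2 JI92 libraries of 2017 (intervals 1.701 to 1.708 and 1.735 to 1.740), against 5.25% and 5.44% in the main set (5.249 to 5.260 and 5.433 to 5.444). At D2 the 2 JI92 libraries of 2017 had stage scores of 2.72 each, against -0.25 and -0.08 in the main set. Their abundant embryo genes took 3.10% and 3.25% of the counts (3.098 to 3.106 and 3.244 to 3.252), against 0.535% and 0.550% (0.534 to 0.537 and 0.549 to 0.552). Without replicate 2 of the JI64 seed coat at D1, the library with embryo-like content, the sets called 19219 and 19222 genes, 1240 of them in opposite directions, the difference between them 6174, and the contrasts within JI64 and JI92 2954 and 10720.

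Single accessions differed widely whatever their class. With libraries as replicates at D1, D3 and D4, the number of genes that differed between 2 accessions ran from 10261 of 39674 (25.9%) for wild JI1794 against domesticated JI92 to 21283 (53.6%) for wild JI261 against Cameor (edgeR). The 2 domesticated accessions, Cameor and JI92, differed at 17272 genes, and the wild accessions differed from each other at 13994 to 17823 genes. PI358617 differed from JI1794 at 14188, from JI261 at 14299, from JI92 at 14723, from JI64 at 17066 and from Cameor at 20729 genes. Without replicate 2 of the JI64 seed coat at D1 each count stayed within 1.5 times its value. The stage scores at D1, D3 and D4 also differed between accessions. JI1794 (-2.47, 2.72 and 3.29) and JI92 (-2.86, 2.105 and 3.97) were close. JI261 (-2.63, -0.20 and 2.17) lay below Cameor (0.02, 2.47 and 3.36). Cameor and JI64 (-0.16, 3.00 and 3.49) were close too but differed at 18251 genes. The part of developmental progress in these counts was not tested, so they do not rank accessions by divergence.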

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

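Of the tests below, those of carried-over tissue, of embryo tissue in each JI64 library at D5, of abundant features and of a state of JI64 at D1, of wild seed coats at D5 and of mapping, the splits of the 5 accessions, and the shufflings of the pair of accessions and of embryo D2 to D5, were chosen only after the result was seen. In 54 sets of accession means, 5 had a value far from the others, where chance gives about 1 in 20, or 2.7.

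In the JI64 seed coats at D1 abundant embryo genes took 6.57% of the counts on average, against 0.0334% to 0.458% in the other 5 accessions, and replicate 2 alone set this value. A few features taking most of the counts are argued against, since without the 5 most abundant ones the seed-coat-enriched share of replicate 2 was 0.0375%, below the lowest other D1 seed coat (5.06%). Embryo tissue carried over into a seed coat sample is also argued against, because the seed-coat-enriched share was 0.323% of that of replicate 1. A wrong label may account for it: the abundant embryo genes reached 0.548 of their share in the JI64 embryo at D1, and the seed-coat-enriched share lay under the highest embryo library (0.0478%). A state of JI64 seed coats at D1 is argued against by its other 2 libraries at this stage, with at least 7.23% (95% exact interval 7.224 to 7.235) in seed-coat-enriched genes, above the lowest of the other accessions (4.83%).

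At D5 the JI64 seed coats held 25.2% of their counts in 5 features, against 5.29% to 7.64% in the other accessions, and 10.1% in loci outside the annotation, against 2.5% to 4.88%, and replicate 1 alone set both means, as replicate 2 lay within the range of the others. Both libraries hold few seed coat transcripts, and the abundant features alone do not account for it, since without them the higher of the 2 seed-coat-enriched shares was 1.71%, below the lowest other D5 seed coat (2.23%). Embryo tissue with the content of the D5 embryos analysed here is argued against as the source for replicate 1. Its abundant embryo genes reached 0.0774 of their lowest share in a D5 embryo, that of JI1794. Diluting the lowest other D5 seed coat to its level needs 0.926. This holds only if the share in a D5 embryo of JI64, which was not analysed here, was not far lower. A state shared by wild seed coats at D5 is argued against by JI261 and JI1794. Their mean seed-coat-enriched share was 1.23 times that of Cameor, JI92 and PI358617. For replicate 2 embryo tissue cannot be told apart from other sources (0.433, where 0.246 is needed): no D5 embryo of JI64 was analysed here, and the bound set beforehand, under 0.5 of the share in the JI64 embryo at D4 (0.300 and 0.0535), does not carry to D5 as that share fell from 41% at D3 to 13.7% at D4. A state of JI64 itself, damaged RNA and an unlabelled tissue stay open as possible sources for both, untested.

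More genes were lower than higher in every wild seed coat, 122 against 58, but another split, JI1794, JI261 and Cameor against JI64 and JI92, leaned further (119 against 30). In the remaining splits 20% to 52.4% of the separating genes were lower in the 3 accessions. Where Cameor and a wild accession were the other 2, this was 20% to 43.2%. For the 47 of the 122 genes that reached a mean of 2 CPM in the embryo, a difference in the seed coat alone is argued against. All 47 had the same sign there, with a median log2 difference 0.940 times that in the seed coat. Where a class had no count, its log2 level was set by the prior count of 2. The ratio therefore does not measure how alike the differences are in size. The cut-off used the mean over both classes, so genes high in the embryos of either class could enter. The rest of the 122 genes stayed under it, and for them the question is open. Poorer mapping of reads from peas other than P. sativum may play a part and cannot be told apart from inherited differences: PI358617 lay nearer the domesticated accessions at 33.6% of the 122 genes (25.3% to 42.7%), as either would allow. With 10 splits of the 5 accessions, 4 gave at least as many separating genes as the real 180 (highest other 274), and in the embryo 5 of 10 gave at least 118 (highest other 504, with JI261, Cameor and JI92 against JI64 and JI1794, several times the real count, which points to a structure of these samples), and the splits are too few for a share under 0.05. The embryo stage scores of JI64 and JI1794 were above those of the other 3 accessions at D3 (4.50 and 5.72 against 0.96 to 4.22) and D4 (5.50 and 5.33 against 3.92 to 4.86), and whether this sets that split apart was not tested.

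In the embryo at D4 the 5 most abundant features of JI64 took 9.75% of the counts, against 22.9% to 27.9% in the other accessions. The Cameor seed coats at D4 had a mean total of 92.39 M counts, against 63.5 M to 71.3 M. For 1902 genes the difference between JI64 and JI92 in the seed coat differed between the main set and the 2017 set, by a test of the difference itself. In the interaction of tissue and class, where 0 genes passed, camera at the preset correlation passed seed-coat-enriched genes (adjusted p = 3.04e-11) and early genes (0.00854), and both calls were lost with an estimated correlation (0.425 and 0.610). Without the 2 JI92 embryos at D3 the median of seed-coat-enriched genes turned from 2.21 to -0.21 (adjusted p = 0.161), and that of early genes went from 0.86 to 0.50 (0.0141, and 0.711 with an estimated correlation). In embryos at D1, which no comparison used, abundant embryo genes took on average 20.6% of the counts in Cameor, 23.1% in JI64 and 1.28% in PI358617. Among the D1 seed coats of accessions other than JI64 the highest mean of an accession was 0.458%.

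For the 3 comparisons of classes each of the 10 splits of the accessions gave 0 genes, the real one included (highest other 0), and with DESeq2 5 of the 10 gave at least the real 2776 (highest other 3164), and the splits are too few for a share under 0.05. Chance is argued against for seed coat against embryo, where 1 of 21 swaps of labels within accessions gave as many as the real 8947 genes (highest other 0), and for D5 against D1 (1 of 21, real 12726, highest other 4172). Chance in the labels of single libraries is argued against for JI64 against JI92 in the main set (1 of 21 shufflings, real 14767, highest other 101) and in the 2017 set (1 of 21, real 14336, highest other 810). For JI1794 against JI92, the pair of accessions with the fewest genes, a fit on the libraries of that pair alone gave 13286 genes (1 of 100, highest other 4944). The libraries of a group may be technical, so these shufflings of accession labels show only that libraries of an accession resemble each other. The smallest seed coat step, from D4 to D5, gave 221 genes (1 of 21, highest other 0). In the embryo D4 to D5 gave 0 genes, as did the other 20 draws (21 of 21), and D2 to D5 gave 12392 (1 of 21, highest other 3). The draws for stage steps shuffled all stage labels within each accession. They therefore test stage effects as a whole and cannot decide on chance at a single step. The count of the seed coat step D4 to D5 also depended on the accession left out.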

How the results depend on the processing

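Stage steps and their alternatives, fits without JI64 libraries that stood apart, and list tests without JI64 (also at D5 alone), the overlap of the tissues for other splits, without the JI92 embryos at D3 or at D4 alone were chosen only after the data were seen. D5 against D1 in the seed coat stayed within 1.5 times its 12726 genes under each of 18 alternatives (10086 to 17766, and 10086 to 12553 when an accession or replicate was left out). Seed coat against embryo gave 7004 to 8586 genes with 1 accession or replicate left out, 13861 with DESeq2 and 16507 with single libraries. The seed coat class comparison gave 0 genes in each left-out fit, 2 without the filter, 2776 with DESeq2, 661 with limma-voom, 12297 with single libraries, 0 without the 3 JI64 libraries, and 14831 with both of these changes. Without the 3 JI64 libraries that accession had no D5. With D5 of every accession and replicate 2 of JI64 at D1 left out, 0 genes passed as well. The embryo comparison gave 2625 with DESeq2 and 13328 with single libraries, and the interaction 2, 97 and 10271 without the filter, with DESeq2 and with single libraries. Single libraries give more residual samples by construction, and for the other changes the cause was not tested. At D3, D4 and D5 the class comparison without the filter gave 18, 11 and 60 genes.

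Equal replicate numbers showed no pairing of libraries of different accessions at the same tissue and stage. The deviations of equal numbers correlated with a median of -0.00116 over 144 pairs of such groups (-0.226 to 0.145). Whether the numbers pair the seed coat and embryo of an accession was not tested. With the number as a replicate block, single libraries gave 12065 genes for the seed coat classes, 13159 for the embryo, 10183 for the interaction and 16484 for seed coat against embryo, close to the fits without it. The block left D5 against D1, JI64 against JI92 and the pairs of accessions within 1.5 times their counts.

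With 1 accession left out, the seed coat steps gave 0 to 1173, 0 to 1865, 0 to 228 and 0 to 624 genes, and the embryo steps 0 to 3060, 0 to 10 and 0 to 1. Without the filter the seed coat steps D1 to D2, D2 to D3 and D4 to D5 gave 259, 615 and 112 genes and the embryo steps D2 to D3 and D3 to D4 gave 0 and 5. With RLE the seed coat step D4 to D5 gave 123 and the embryo step D3 to D4 gave 5. Without the 3 JI64 libraries D2 to D3 gave 2685 and D3 to D4 1088 in the seed coat. Embryo D2 to D5 gave 9220 to 11850 genes with 1 accession left out. Without 1 JI64 library at D1 the difference between the main set and the 2017 set gave 6174 genes, and 2017 against the main set 2954 in JI64 and 10720 in JI92. The cause was not tested.

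For gene lists, camera with an estimated correlation and fry gave 0.970 and 0.9975 for seed-coat-enriched and early genes between seed coat classes, 0.798 and 0.947 for seed-coat-enriched genes between embryo classes, and in the interaction 0.425 and 0.368 for seed-coat-enriched and 0.610 and 0.396 for early genes. Between tissues they gave 0.465 and 0.141 for early genes, 0.292 and 0.0838 for late genes, and 0.292 and 0.141 for loci outside the annotation, and the estimated correlation gave 0.0953 for embryo-enriched genes. Without the JI92 embryos at D3 and at D4 alone camera gave 0.147 and 0.129 for seed-coat-enriched genes between embryo classes, and 0.161 and 0.255 in the interaction. At D4 alone it passed 2 lists that did not pass before, early genes between embryo classes (0.0426) and late genes in the interaction (0.0271), with 0.726 and 0.547 with an estimated correlation. With JI64 left out the median of early genes between seed coat classes moved to 0.32 (camera 8.00e-06, and 0.722 with an estimated correlation) and that of loci outside the annotation turned to -0.29. Without the 3 JI64 libraries, and so without JI64 at D5, embryo-enriched genes passed between seed coat classes (0.0232, and 0.770 with an estimated correlation). The cause was not tested. At D5 without JI64 seed-coat-enriched genes and loci outside the annotation passed (0.000849 and 0.0359, with 0.697 for both with an estimated correlation), and late genes passed as before (0.0359, and 0.697 with an estimated correlation). With the share of embryo taken from the median gene, mixtures of D1 seed coat and D5 embryo gave late genes a mean level of 2.70 to 3.05, with 145 to 170 of 300 above the mixture, a computation also chosen after the data were seen. The lower of these counts were near the even split that noise alone would give. The position of PI358617 at genes lower in wild was 20% at 10 CPM or more. Named genes held their direction in 128 alternatives and their call in 125: Ps_DOR2genes.8646 had adjusted p of 0.0702 and 0.0826 with single libraries without and with the replicate block (edgeR), and Ps_DOR2genes.57123 0.108 with limma on log2(FPKM + 1).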

Other observations

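The tests in this part were all chosen after the data were seen. Some features had no count in any library of 1 accession and at least 1 CPM in each of the other 5, over both tissues of the main set. Among annotated genes there were 29 such features in JI261, 14 each in Cameor and PI358617, 6 in JI64, 2 in JI1794 and 0 in JI92. Among loci outside the annotation there were 14 in JI261, 13 in PI358617, 7 in Cameor and 5 in JI1794. JI261 had the fewest libraries (14, against 17 to 20) and the lowest total (888 M counts, against 1167 M to 1411 M), which makes a count of 0 in every library easier to reach, so the ranking is not one of equal sampling. By another measure, a level over 16-fold below that of every other accession, the annotated genes numbered 78 in Cameor, 68 in PI358617, 62 in JI261, 26 in JI1794, 22 in JI64 and 16 in JI92. The limit of 3 counts ranged from 0.00213 CPM in Cameor to 0.00338 CPM in JI261.

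Genes of the Psat1g to Psat7g series that separate wild from domesticated seed coats did not lie next to each other in identifier order more than by chance, with 1 adjacent pair among 82 genes against 0.450 in 1000 shufflings (permutation p = 0.367). The split of JI1794, JI64 and JI92 against JI261 and Cameor had 7 adjacent pairs among 167 genes, against 1.86 (permutation p = 0.002, 1 of 10 splits examined).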
